A study of Homo sapiens with 6 samples.

How the data were processed

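Total RNA of 6 samples, 3 of H9-derived NSC and 3 of neurons differentiated from such cells, was profiled on miRNA arrays, with a single dye per sample. Per the labels, 4 to 8 µg of total RNA was size fractionated to keep RNA under 300 nt, a poly(A) tail was added, and an oligonucleotide tag ligated to the tail was stained with Cy3 or Cy5 by a service provider. The tag does not depend on the RNA's sequence, so other short RNAs in the fraction are labelled too. Per the labels, neurons 1 and 3 and NSC 1 carried Cy3, and neurons 2 and NSC 2 and 3 carried Cy5. The scanner, the image software and the method behind the authors' normalization are not given in the sources used here.

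The deposited scanner tables give, per the file headers, the mean intensity of each spot and the SD of the brightness within it, on a linear scale with the background not subtracted. The authors also deposited a matrix of normalized intensity for 1090 miRNAs, and the values of 870 of these in a second table, where 870 of 870 rows were identical to the matrix. In both, a point followed by 3 digits groups digits and is no decimal point. Of 6540 values 343 carry such a point, and 984 is the highest without one. With the point removed, the columns had rank correlations of 0.947 to 0.995 with the scanner intensities of the same samples, across miRNAs. With it as a decimal point, the correlations were -0.508 to 0.947. The points were therefore removed throughout. The medians of the matrix columns were 13.0, 12.0 and 12.0 for neurons 1 to 3 and 11.0, 10.5 and 11.0 for NSC 1 to 3, on a linear scale with no centring seen, and how the authors scaled the samples stays unknown.

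The scanner intensities were the starting point. They come without a background column, so the background was corrected with limma's normexp model fitted to the 406 empty spots of each array (offset 50). This departs from the plan made before the data were examined, which foresaw normexp on separate foreground and background values. The 3 spots of a probe were averaged, and values were taken to log2 and quantile normalized over the 1090 human miRNA probes. Control spots stayed out of the normalization and the test. A probe was called detected where its mean intensity lay above the 95th percentile of the array's empty spots. These limits were 97.5, 67.2 and 170 for neurons 1 to 3 and 163, 49.5 and 65.8 for NSC 1 to 3, so a given intensity is above background on some arrays and not on others. A miRNA was tested if detected in at least 3 of the 6 samples, which left 293 of 1090. The number of arrays limits the precision. The median coefficient of variation of repeat spots ran from 7.98% (neurons 3) to 19.3% (NSC 1).

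Groups were compared with limma (lmFit and eBayes with an intensity trend, two-sided, group as the only term), and miRNAs with a Benjamini-Hochberg adjusted p under 0.05 were called. Changes are neurons minus NSC on the log2 scale. P-values measure the spread between the samples, which the series calls biological repeats. For a called miRNA detected in no sample of the dimmer group, the fold is given as a lower bound, unless it lay too close to the limit for a bound. The bound sets the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest normalized value among detected probes and the probe's own value. The offset of 50 compresses changes of dim miRNAs.

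A set of 18 miRNA lists was fixed before the data were examined. They were neuronal, let-7, miR-125 with miR-99 and miR-100, pluripotency, C19MC, miR-17~92, DLK1-DIO3, miR-181, miR-34 with miR-449, miR-29, miR-30, miR-15/16, miR-23/27/24, glial, mesenchymal and fibroblast, epithelial, blood and endothelial, and muscle and liver miRNAs. The 11 lists with at least 3 tested members were tested with limma's camera (preset correlation 0.01, two-sided, adjusted over these lists), with an estimated correlation and with fry beside it. With an estimated correlation 0 of the 11 lists passed, while 2 had an unadjusted p under 0.05, and fry called 6. The miRNAs named in the text were chosen by a rule fixed at the same time. It takes the 12 largest rises and 12 largest falls among called miRNAs whose groups do not overlap, the 2 members of each tested list with the smallest adjusted p, and a fixed set that holds miR-124, miR-9, miR-9*, miR-125b, let-7a, miR-302a, miR-302b, miR-367, miR-371-5p, miR-372, miR-17, miR-92a, miR-181a, miR-181a*, miR-153, miR-133b, miR-7, miR-132 and miR-21. Other miRNAs named in the text (let-7d*, miR-149, miR-106a, miR-20a, miR-219-2-3p, miR-122, miR-486-5p, miR-1826, miR-1975, miR-1308, miR-1280, miR-720, miR-575, miR-31, miR-135a, miR-98, miR-363*) were chosen after their values were seen.

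Names and target sequences are those of the array's design. Names were matched to RefSeq genes (human assembly GRCh38.p14) for 280 of the 293 tested miRNAs, and no coordinates are given because the deposited files name no genome build. Of the 93 called miRNAs, 21 have a probe within 2 edits of another probe on the array, and their values are uncertain because related miRNAs can hybridise to both.

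No file names a slide. Whether samples of opposite dye shared one was inferred from the errors of repeat spots, as the rank correlation of each spot's deviation from its probe's mean. It was 0.354 for neurons 2 with NSC 1 and 0.264 for neurons 3 with NSC 3, and at most 0.107 for every other pair. A value over 0.2 was read as a shared slide. Whether samples on a shared slide affected each other's signal was not tested.

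The steps were tested on simulated data for neurons against NSC, with 271 miRNAs tested. Of miRNAs changed by 1 on the log2 scale, 1 of 18 was called, of those changed by 2, 11 of 17, and of those changed by 4, 16 of 16, while 2 of 220 unchanged miRNAs were called. Median recovered sizes were 0.55, 1.41 and 2.64, so changes are understated and a change of 1 is mostly missed. The simulation gave both groups the same base profile and planted as many rises as falls. It therefore did not test errors from the choice of scaling, and its count of false calls does not cover them. Alternatives covered the scaling, background, filter, combination of spots, deposited values, dye, slide and replicate blocks, fit, threshold and the removal of each sample. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.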

Results

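MicroRNA abundance was measured in 6 RNA samples made from H9, an established human embryonic stem cell line. In 3 samples the cells were neural stem cells (NSC) derived from H9 and kept in medium with the growth factor bFGF. In the other 3 samples the NSC had been differentiated further, with neurotrophic factors, into cells that the labels call neurons. Each sample was hybridised to an oligonucleotide array that carried 1090 probes for human miRNAs, each printed as 3 spots. The series calls the samples of a group biological repeats and gives no further detail on how the cultures were kept apart.

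The arrays differed in brightness. Probes above the background of the empty spots made up 33.7%, 31.7% and 24.5% of all miRNA probes in neurons replicates 1 to 3 and 27.3%, 15.8% and 16% in NSC replicates 1 to 3. The mean number was 326 ± 52.5 (SD, n = 3) in neurons and 215 ± 72.2 (SD, n = 3) in NSC, a difference that did not pass the test (exact two-sided permutation p = 0.2, where 0.1 is the smallest this design allows). Summed miRNA signal above background was 708841 ± 103722 intensity units in neurons and 223039 ± 170905 in NSC (SD, n = 3, exact two-sided permutation p = 0.1, the smallest possible). NSC replicate 2 was the dimmest array, with a summed signal of 83231. Cy5 was carried by neurons 2 and by NSC 2 and 3, so dye and group were partly confounded. In each group the Cy5 samples had the lower summed signal, 592999 in neurons 2 and 83231 and 172324 in NSC 2 and 3. Within each dye the neuron samples had the higher, for Cy3 with 740426 and 793098 against 413561 in NSC 1. All 3 neuron samples detected 249 miRNAs and all 3 NSC samples 144, of which 139 were shared. There were 30 miRNAs detected in all 3 neuron samples and in no NSC sample, and 0 with the opposite pattern. Normalized log2 intensities of the tested miRNAs correlated, across miRNAs, at r = 0.917 to 0.969 between neuron samples, at 0.908 to 0.934 between NSC samples, and at 0.561 to 0.727 between the groups. Probes are not independent replicates, so these coefficients are descriptive.

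**Figure D1:**
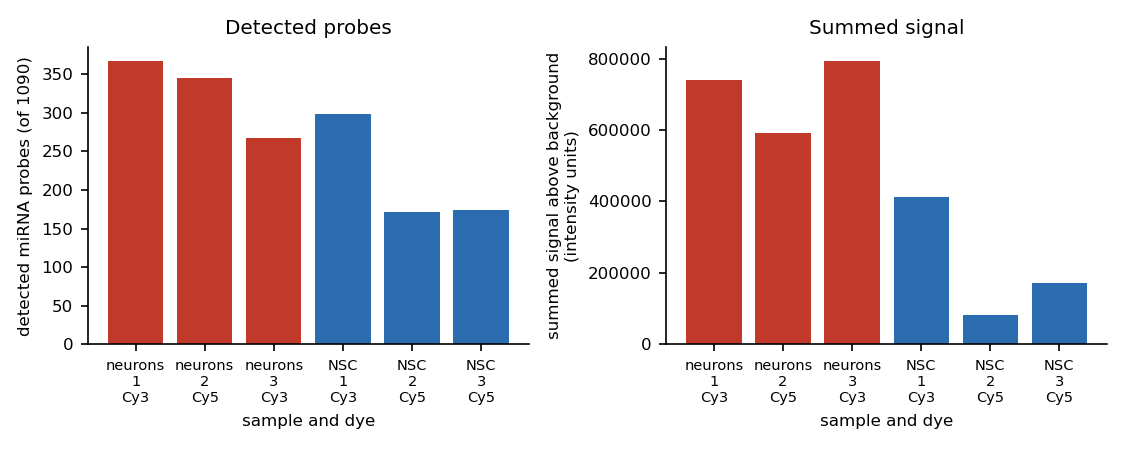
Detected miRNA probes (left) and summed miRNA signal above background (right) for each sample, 1 bar per sample, neurons in red and NSC in blue, with the dye below. Summed signal ran from 592999 to 793098 in the neuron samples and from 83231 to 413561 in the NSC samples.

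The comparison of neurons with NSC asks which miRNAs change as human neural stem cells become neurons. Differentiated cells had far more of miR-9, miR-7 and the let-7 family. miR-9, which is abundant in the developing and adult brain, was higher by 8.31 on the log2 scale (SE 0.36, n = 3 per group), measured against NSC values of which 1 of the 3 lay above background, and let-7a, a member of the family that restrains proliferation and stem cell programmes, by 5.54 (SE 0.43). The miRNAs that fell in neurons included miR-199a-3p, with a log2 change of -6.34 (SE 0.72), and miR-214, with -5.47 (SE 0.60), both known from mesenchymal cells. Members of the miR-17~92 group, which promotes proliferation, fell by less, with log2 changes of -1.30 (SE 0.26) for miR-17 and -1.47 (SE 0.26) for miR-92a. In all, 57 of 293 tested miRNAs were higher in neurons and 36 were lower (limma moderated test, two-sided, Benjamini-Hochberg adjusted p under 0.05). Without NSC replicate 3 the count of those higher was 36. Fitted changes of at least 2-fold made up 40 of the 57 and 35 of the 36, or 36 of the 57 and 35 of the 36 with miRNAs undetected in the dimmer group at their bound.

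Among the neuronal miRNAs, a list of miRNAs enriched in neurons or raised in neuronal differentiation, 15 of 23 tested members rose, 1 fell and 7 did not pass the test. Adjusted over the list alone, 16 rose and 1 fell. The 2 strands of the miR-9 hairpin were both among the 3 largest rises. miR-9 (target UCUUUGGUUAUCUAGCUGUAUGA, genes MIR9-1, MIR9-2 and MIR9-3) was detected in 1 NSC sample (adjusted p = 1.28e-07, limma). It had the top rank on all 3 neuron arrays, to which quantile normalization assigns 1 value, so its SD of 0 in neurons is a product of that step. miR-9* and miR-7 were detected in no NSC sample and were at least 113-fold and at least 151-fold higher in neurons (limma adjusted p = 2.42e-07 and 2.28e-07). Bounds on a fold hold under quantile normalization, and the lowest fitted log2 changes over all settings, 5.70 for miR-9* and 6.22 for miR-7, lay below them. miR-124 (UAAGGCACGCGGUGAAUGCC), the classical neuron-enriched miRNA, rose by 3.47 (SE 0.44, adjusted p = 0.000296) from a level already detected in all 3 NSC samples. miR-132, known to respond to neuronal activity, rose by 2.58 (SE 0.48). The member that fell was miR-149*, with a log2 change of -2.37 (SE 0.59), while miR-149 itself, detected in 1 NSC sample, rose by 1.60. The name marks miR-149* as the less abundant strand of its hairpin, but in NSC its probe was the brighter (mean 9.63 against 6.33 for miR-149, normalized log2 intensity). The list median was 1.04, or 0.50 with undetected members placed at their bound where they had a bound and at their fitted change otherwise. That 0.50 is the fitted change of miR-135a, which had no bound, so it is not a lower limit on the median. The list stood above the other tested miRNAs (camera adjusted p = 5.34e-06). With an estimated correlation between members, adjusted p = 0.118, and with only miRNAs detected in all 6 samples tested, camera adjusted p = 0.134. The list median turned negative, to -0.29, when samples were scaled to the 75th percentile of the probes detected in all samples, a scaling that moved the median of all tested miRNAs to -1.15. After a GC trend was removed from each sample, miR-135a, named after its values were seen, passed in the opposite direction, going from a fitted 0.50 to -1.49 (adjusted p = 0.00283, limma). It was detected in no NSC sample and lay too close to the limit for a bound on the fold. miR-153 was detected in 1 sample and was not tested.

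In the let-7 family, 9 of 10 tested members rose and 0 fell, and the same counts held adjusted over the list alone. let-7f, let-7d and let-7g were detected in no NSC sample and were at least 49.5-fold, 34.3-fold and 27.6-fold higher in neurons under quantile normalization, with lowest fitted log2 changes of 4.30, 4.84 and 4.16 over all settings. let-7c rose by 5.85 (SE 0.42, adjusted p = 5.24e-06, limma), let-7i by 4.13 and let-7e by 3.87, where let-7c and let-7i were each detected in 2 NSC samples. The member that did not pass was let-7d*, with a log2 change of 0.27. miR-98, also named after its values were seen, was detected in no NSC sample and was at least 1.52-fold higher in neurons. After removal of the GC trend its fitted change went from 1.43 to -0.40 (adjusted p = 0.403, limma). The list median was 4.80, or 4.46 with undetected members at their bound (camera adjusted p = 7.59e-08), and adjusted p = 0.213 with an estimated correlation. Without the filter on dim probes, which brought in 9 members not tested otherwise, the median was 0.27 (camera adjusted p = 4.51e-08). let-7 probes differ from their nearest relative by 1 or 2 bases, so the values of single members are uncertain and may share signal. Of the family of miR-125, miR-99 and miR-100, which lies next to let-7 genes in the genome, 4 of 8 tested members rose and 0 fell, or 5 rose adjusted over the list alone. miR-125a-5p rose by 3.00 (SE 0.49, adjusted p = 0.0013) and miR-125b by 2.10 (SE 0.27). The miR-125b call was lost under cyclic loess, and its lowest change over all settings was 1.10. The list median was 1.57 (camera adjusted p = 0.00732, and adjusted p = 0.213 with an estimated correlation). Both families kept a positive median under all 5 scalings tried.

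Among the mesenchymal and fibroblast miRNAs, a list of markers of another cell type, 7 of 10 tested members fell and 0 rose, also adjusted over the list alone. miR-199a-3p (ACAGUAGUCUGCACAUUGGUUA) and miR-214 (ACAGCAGGCACAGACAGGCAGU) fell the most, with adjusted p = 0.000139 and 0.000114. miR-199a-3p was detected in all 3 NSC and 2 neuron samples. miR-199a-5p had a log2 change of -3.90 (SE 0.81), and miR-145 and miR-143, known from smooth muscle, had -2.74 (SE 0.55) and -2.08 (SE 0.48). Each of these 3 was detected in 1 neuron sample. miR-221 and miR-222, which share a cluster and target cell cycle inhibitors, had -2.48 (SE 0.49) and -2.27 (SE 0.47). Both calls were lost, among other settings, with the 75th percentile over all probes and without normalization. Their smallest falls over all settings were -0.27 and -0.26. The miR-145 and miR-143 calls were also lost without normalization. miR-21, abundant in cultured fibroblasts, did not pass, with -0.46 (SE 0.70, 95% interval -2.01 to 1.09, adjusted p = 0.609). The list median was -2.38 (camera adjusted p = 0.000216, and adjusted p = 0.268 with an estimated correlation), and it was negative under all 5 scalings. The list did not pass with only miRNAs detected in all 6 samples tested (camera adjusted p = 0.134). Without the filter on dim probes, which brought in 17 further members, the median was -0.10 (camera adjusted p = 0.00108).

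Of miR-17~92 and its paralogs, 9 of 16 tested members fell and 0 rose, and 11 fell adjusted over the list alone. miR-363 had the largest fall, -3.32 (SE 0.43, adjusted p = 0.000342), followed by miR-20b with -2.01 (SE 0.31). Both calls were lost with the 75th percentile over all probes and without normalization. Their smallest falls over all settings were -1.31 and -0.23. miR-17, miR-106a, miR-20a and miR-20b differ by few bases and may share signal. The list median was -1.29 (camera adjusted p = 8.24e-05, and adjusted p = 0.213 with an estimated correlation), but it was 0.35 without normalization between samples, where the median of all tested miRNAs was 0.91. There, miR-17 and miR-92a changed sign to 0.33 and 0.14. With the authors' deposited normalized values miR-17 had -0.61 and did not pass (adjusted p = 0.0908, limma, within a range of 0.000933 to 0.973 over all settings). The list call was lost under 2 scalings, with camera adjusted p = 0.0508 without normalization and 0.0523 with the percentile of the probes detected in all samples.

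Other large falls lay outside the lists. miR-1246 had a log2 change of -4.16 (SE 0.62), miR-1275 -3.06 (SE 0.47), miR-1915 -2.97 (SE 0.49) and miR-1979 -2.41 (SE 0.36). Each of these calls was lost with the 75th percentile over all probes and without normalization, among other settings for some. In the same order, their smallest falls over all settings were -2.13, -0.80, -0.62 and -0.21. miR-1246 and miR-1979 are known to match U2 small nuclear RNA and a Y RNA. The targets of miR-1275, miR-1915 and miR-149* are rich in G and C (70.6%, 90% and 76.2%), and 12 of the 36 miRNAs that fell had a GC content of 60% or more, against 9 of the 57 that rose and 84 of all 293 tested. Among the called miRNAs, the association of a GC content of 60% or more with direction did not pass (Fisher's exact test, two-sided, p = 0.0736), which leaves it open. Mean GC content was 58% in the falls and 47.8% in the rises, and 79.4% and 63.6% among those of 60% or more. After a GC trend was removed from each sample, miR-1275, miR-1915 and miR-149* had changes of -2.50, -1.36 and -1.55. There miR-149* no longer passed (SE 0.51, adjusted p = 0.0547, limma). The 6 probes for 5S ribosomal RNA moved the same way, with a median log2 change of -2.56, and of -1.32 to -3.38 under the 5 scalings. Without normalization, and with the percentile over all probes, 1 of the 6 did not go down. The largest rise outside the lists was that of miR-4324, 3.65 (SE 0.85, adjusted p = 0.0106), detected in 2 NSC samples. Its target shares a run of 15 bases with that of miR-125b, which also rose, so the probes may share signal.

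**Figure D2:**
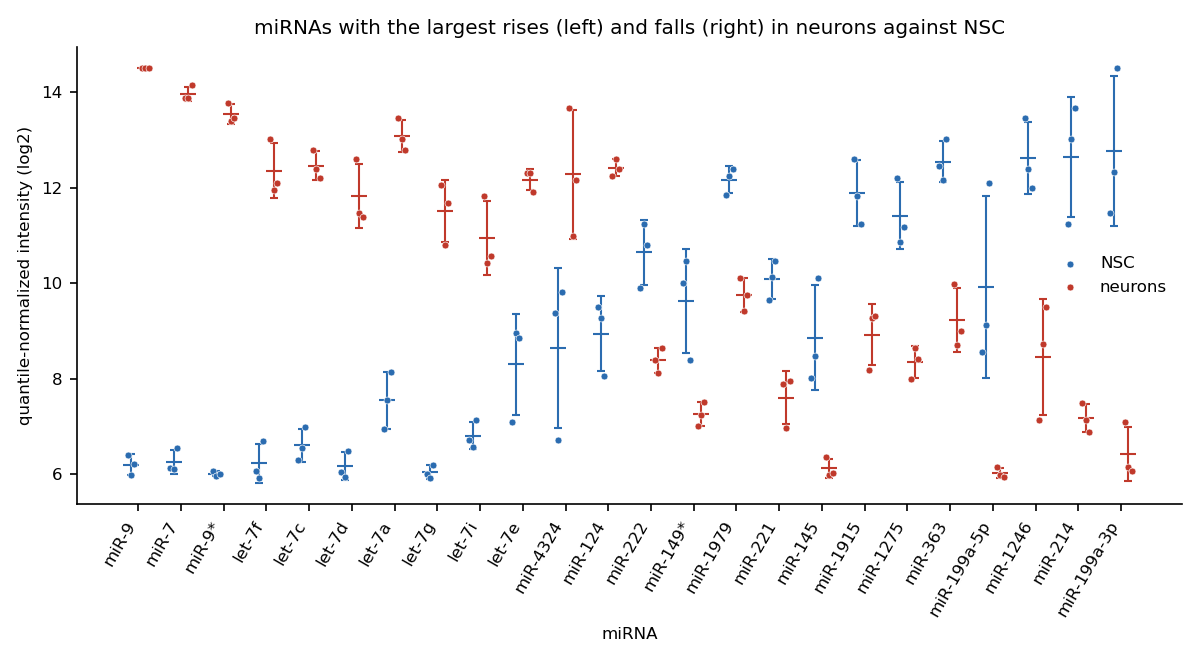
Quantile-normalized log2 intensity of the 12 miRNAs with the largest rises and the 12 with the largest falls among the called miRNAs, ordered by change, with 1 dot per sample and bars for the mean ± SD (n = 3 per group), NSC in blue and neurons in red. The groups do not overlap for any of them, and miR-9 lies at 14.51 in every neuron sample and at 5.98 to 6.41 in NSC.

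The remaining lists did not stand apart from the other tested miRNAs under quantile normalization with dim probes left out, while the lists of the miR-181 and miR-15/16 families did under some other settings. In the miR-181 family, recalled as followed up in the study's own paper and so not independent evidence, 1 of 6 tested members passed, miR-181a, which rose by 1.16 (SE 0.25, adjusted p = 0.0062). The miR-181a call was lost, among other settings, under cyclic loess and with the percentile of the probes detected in all samples. Its lowest change over all settings was 0.38. miR-181d had 2.19 (SE 0.76, adjusted p = 0.0512), the list median was 1.09 (camera adjusted p = 0.157), and miR-181a* was detected in 2 samples and not tested. The list passed without the filter on dim probes (camera adjusted p = 0.00266), with detection in all 6 samples (0.00666) and with fry (0.0425), which does not compare a list with other miRNAs, and adjusted p ran up to 0.852 over its settings. miR-181d passed in 11 other settings, with adjusted p from 0.000267 to 0.889 over all. In the miR-15/16 family 2 of 4 fell, miR-15b with -1.43 (SE 0.37) and miR-16 with -1.29 (SE 0.39), and both changed sign without normalization, to 1.10 and 1.06, and with the percentile over all probes, to 0.76 and 0.71. With the authors' deposited normalized values miR-16 did not pass (-1.07, adjusted p = 0.0616, limma, within 0.00608 to 0.496 over all settings). That list had a median of -0.76 (camera adjusted p = 0.345), which turned to 1.08 and 0.73 without normalization and with the percentile over all probes. It passed without the filter on dim probes (median -0.14, camera adjusted p = 0.0142) and with the GC trend removed (median -1.28, camera adjusted p = 0.0274), with adjusted p up to 0.755 elsewhere. In the miR-30 family 0 of 8 passed (median 0.20, camera adjusted p = 0.543), with 1.11 for miR-30e and 0.24 for miR-30c-2*. In the miR-23/27/24 clusters 0 of 5 passed, with 0.31 for miR-23a and -0.71 for miR-27b. There the median was 0.07, the mean -0.07 and the direction of the test downward (camera adjusted p = 0.955), and the median was -0.17 under cyclic loess. Of the glial miRNAs, 1 of 8 rose and 2 fell (median -0.37, camera adjusted p = 0.645), with a median of 1.19 without normalization and 0.84 with the percentile over all probes. The members that fell, miR-143 and miR-145, are also on the mesenchymal list, and the member that rose was miR-219-2-3p, known from oligodendrocytes, with 2.30 (SE 0.75). In the imprinted DLK1-DIO3 cluster 1 of 8 rose, miR-487b, with a fitted change of 0.67 (SE 0.18), and miR-379 had 0.39 (adjusted p = 0.0512). Both were detected in all 3 neuron samples and no NSC sample, too close to the limit for a bound on the fold. The cluster's median was -0.18 while its test pointed upward (camera adjusted p = 0.955). That median was positive under 3 other scalings, from 0.05 under cyclic loess to 0.79 without normalization. The sign of miR-487b turned to -0.93 (adjusted p = 0.285) with the percentile of the probes detected in all samples.

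**Figure D3:**
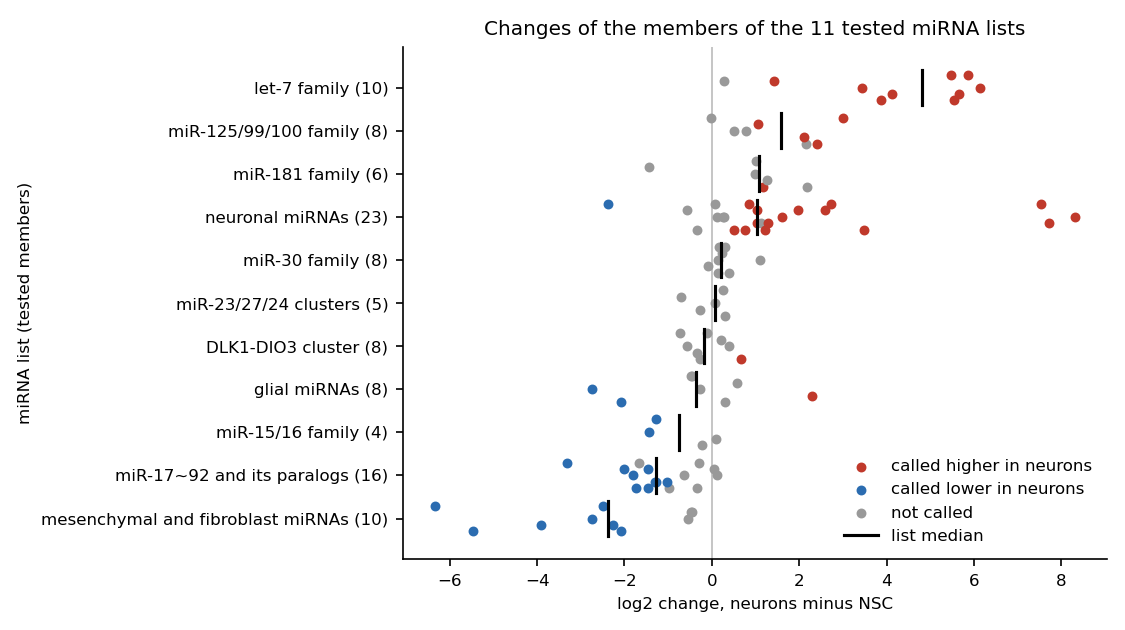
Log2 change (neurons minus NSC) of each tested member of the 11 lists with at least 3 tested members, 1 dot per miRNA, red where called higher, blue where called lower and grey where not called, with a black line at the list median. The medians run from -2.38 for the mesenchymal list to 4.80 for the let-7 family under quantile normalization; the medians of 6 of the 11 lists change sign under at least 1 other scaling, those of the let-7, miR-125, miR-181, miR-30 and mesenchymal lists under none of the 5.

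miRNAs of pluripotent cells were mostly not detected in either group. miR-302a, miR-302b, miR-367 and miR-372 were detected in 0 of 6 samples, and of 17 probes for the groups of miR-302, miR-367 and miR-371 to miR-373 only miR-371-5p was tested (-0.23, SE 0.18, adjusted p = 0.345). Of the 47 probes for C19MC, a primate cluster active in placenta and embryonic stem cells, 0 were tested and 1 was detected in any sample. Too few members were tested for 5 further lists. These were the family of miR-34 and miR-449 (2 tested, 0 called), the miR-29 family (2 tested, 0 called), epithelial miRNAs (1 of 19 tested, 0 called), blood and endothelial miRNAs (2 of 15 tested, 1 called) and muscle and liver miRNAs (2 of 10 tested, 1 called). The 2 called were miR-486-5p, at least 1.11-fold higher, and miR-122, at least 1.07-fold higher in neurons, both detected in no NSC sample and named after their values were seen. miR-133b was detected in 2 samples and was not tested.

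All 93 called miRNAs had the 3 quantile-normalized values of one group above the 3 of the other, as did 136 of the 293 tested (46.4%). Chance gives 10% for exchangeable samples, but the filter let in 30 miRNAs detected in all 3 neuron samples and in no NSC sample, which favours separation. Of the 93, 18 were detected in no sample of the dimmer group and had a bound on the fold. Others, among them miR-135a and miR-487b, were likewise detected in no sample of that group but lay too close to the limit for a bound. All changes are relative to the scaling, since the median of all tested miRNAs was -0.12 under quantile normalization, -0.03 under cyclic loess, -1.15 and 0.56 with the percentile over probes detected in all samples and over all probes, and 0.91 without normalization. Relative to that median, the let-7 family stood at 4.34 to 5.41 over the 5 scalings (4.92 under quantile normalization) and the miR-125 family list at 1.05 to 2.54 (1.70). The neuronal list stood at 0.86 to 1.17 (1.17), the miR-17~92 list at -1.40 to -0.56 (-1.16) and the mesenchymal list at -2.25 to -1.54 (-2.25). The percentile scalings and no normalization differ only by a constant per sample, so they give the same relative values by construction. Without the filter on dim probes the medians of the neuronal, miR-125 family and miR-17~92 lists were 0.29, 0.78 and -0.32. The split of calls followed the scaling, with 23 higher and 25 lower under cyclic loess, 29 and 101 with the percentile over probes detected in all samples, 69 and 5 over all probes, and 64 and 3 without normalization. Direction was the same under all 5 scalings for 34 of the 57 miRNAs called higher and 20 of the 36 called lower. A call in each of the 5 held for 23 of those higher, among them miR-9, miR-9*, miR-7, miR-124, miR-132 and let-7a, and for 3 of those lower, miR-199a-3p, miR-199a-5p and miR-214.

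Dye and slide were checked as batches, because both held samples of both groups. With dye as a block, 47 miRNAs were higher and 36 lower. Within the Cy3 samples 19 were higher and 17 lower, and within the Cy5 samples 20 and 6, each with a single sample in 1 group that is assumed to vary like the others. Correlated spot errors placed neurons 2 with NSC 1, and neurons 3 with NSC 3, on shared slides with opposite dyes. With the shared slide as a random block 53 were higher and 34 lower. The let-7 median was 4.75 with dye as a block, 5.44 within Cy3, 4.16 within Cy5, and at least 4.04 on each slide. With dye as a block, within Cy3, within Cy5 and on the 2 slides, the medians were -2.34, -1.56, -3.10, -2.16 and -2.82 for the mesenchymal list and -1.34, -1.14, -1.48, -1.52 and -1.05 for the miR-17~92 list. In the same order they were 0.93, 1.07, 0.77, 0.75 and 0.98 for the neuronal list and 1.36, 1.62, 1.09, 0.96 and 1.24 for the miR-125 family list.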

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

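Alternatives were fixed before the data were examined, except the smooth background map, the removed GC trend, the 4 samples on shared slides and the quantile normalization over tested miRNAs. Against 57 miRNAs higher and 36 lower in neurons, the counts moved by over 1.5 times in at least 1 direction under these settings: cyclic loess (23 higher), the 75th percentile over probes detected in all samples (29 and 101), over all probes (5 lower), no normalization (3 lower), no filter on dim probes (31 and 19), detection in all 6 samples (16 higher), Cy3 alone (19 and 17), Cy5 alone (20 and 6), without NSC replicate 3 (36 higher) and adjusted p under 0.01 (24 and 19). The last is a stricter threshold, the dye subsets hold 3 samples each, the filters change how many miRNAs are tested, and the cause was not tested for the others. Of the 93 calls, 93 had the same sign under cyclic loess, 84 with the percentile over all probes, 77 without normalization, 70 with the percentile over probes detected in all samples and 89 with the GC trend removed, where miR-135a was called in the opposite direction (-1.49). Among the miRNAs named by rule, the reversed values were miR-487b at -0.93 (percentile over probes detected in all samples), miR-15b at 0.76 and miR-16 at 0.71 (over all probes), and miR-15b at 1.10, miR-16 at 1.06, miR-17 at 0.33 and miR-92a at 0.14 (no normalization), each without passing the test. Leaving out 1 sample at a time gave 36 to 55 higher and 27 to 37 lower, and kept 64 (without NSC replicate 3) to 83 (without neurons replicate 1) of the 93 calls, with 70 kept without neurons 3 and without NSC 2. Among the miRNAs named by rule, these fits lost miR-16 in 5 of 6 cases (adjusted p = 0.0582 without NSC 1, 0.0681 without NSC 2, 0.077 without NSC 3, 0.0964 without neurons 2 and 0.106 without neurons 3), miR-15b without neurons 3 (0.0698) and NSC 3 (0.0615), and miR-487b without neurons 3 (0.0588) and NSC 2 (0.0511). They gained miR-181d (0.00814) and miR-30e (0.0446) without NSC 1, and miR-379 (0.0431) without NSC 2. The 5 list calls became 0 with an estimated correlation, and were 4 to 7 in every other setting, with 5 in each fit without 1 sample. The settings with more than 5 list calls gained the miR-181 list, the miR-15/16 list or both. Detection in all 6 samples left the neuronal and mesenchymal lists at camera adjusted p = 0.134. Samples with the same number deviated from their group means with correlations of -0.01, 0.30 and -0.12, against -0.23 to 0.27 for samples with different numbers. The deviations of the 3 samples of a group sum to 0, so these values depend on each other. They cannot tell whether the numbers pair samples. The replicate block gave 64 higher and 42 lower. Signal over background limits the dim miRNAs, since 647 of 1090 were detected in no sample.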

Other observations

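The tests on 5S ribosomal RNA, on dye and slide for the mesenchymal list and on the 2 parts of the GC pattern were chosen after the results were seen. Some probes of the array are listed as miRNAs but match other short RNAs, and 7 of these, picked after their values were seen and not a tested list, are given here. miR-1826, whose sequence is known to match 5.8S ribosomal RNA, had a log2 change of -1.66 (SE 0.25, limma adjusted p = 0.000791). Unlike miR-1979 and miR-1246, it did not keep its direction under all 5 scalings. miR-1979, known to match a Y RNA, had -2.41, and miR-1246, known to match U2 small nuclear RNA, had -4.16. Neither miR-1826 nor miR-1979 had a RefSeq gene under its name. After quantile normalization, all 3 were lower in each of the 3 neuron samples than in any NSC sample. In the scanner intensities before normalization the groups overlapped for each of the 3. The other 4 did not pass the test: miR-1975, also a Y RNA match, had -0.79 (adjusted p = 0.146), and the tRNA-like miR-1308, miR-1280 and miR-720 had -0.97, -0.52 and -0.39 (adjusted p = 0.152, 0.345 and 0.537).

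As a check on the counts of called miRNAs, the 6 samples were split into 3 and 3 in all 10 ways. The real split gave 93 calls and the highest of the others gave 0, so 1 of the 10 splits reached the real count. Every other split mixes the groups, so a large group difference of any source widens its residual spread and leaves few calls. No conclusion on the source of the difference is drawn from this contrast. With 10 splits a share under 0.05 cannot be reached.

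The first pattern is a trend of change with GC content. Across all 293 tested miRNAs, change and GC content of the target had a rank correlation of -0.315, and of -0.293 among the 200 not called. These miRNAs are not independent. Among the called miRNAs, the association of a GC content of 60% or more with direction did not pass (Fisher's exact p = 0.0736), which does not show that there was none. After a trend on GC content was removed from each sample, 75% of the 36 falls were still called, between the bounds set in advance. For the 24 falls with a GC content under 60% the tables argue against the removed trend as the cause, since its removal moved 15 of them further from 0 and the other 9 toward 0 by at most 0.194, less than the smallest SE among the 24 (0.244). The direction of these shifts largely follows from the negative sign of the trend, so they speak only to that trend and not to other effects of GC content. For those of 60% or more a GC trend between the arrays may account for the calls, since 33.3% (4 of 12) stayed, and their median change went from -2.11 (median SE 0.49) to -0.92 (median SE 0.39). Of the 8 calls that ended there, 7 shrank by more than their SE, while miR-575 and, among the 24, miR-363* missed the threshold narrowly, since miR-575 went from -2.24 (SE 0.67) to -1.96 (SE 0.66, adjusted p = 0.0571) and miR-363* from -1.03 (SE 0.35) to -0.99 (SE 0.34, adjusted p = 0.0661). A greater share of structural RNA fragments in the NSC samples also stays open as a hypothesis, since the 5S probes had a median change of -2.56. Relative to the median of the tested miRNAs it was -2.23 to -2.83 under the 5 scalings. The percentile scalings and no normalization give the same relative value by construction. Some NSC values were held at the top of the quantile range. A biological difference between NSC and neurons was not tested apart from the GC trend and such fragments.

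The second pattern is the set of 7 mesenchymal miRNAs higher in NSC than in neurons. Dye or slide differences as the whole cause are argued against by the 2 shared slides, which had opposite dyes, since the median of all 10 tested members of the list was -2.16 on one and -2.82 on the other, with 9 of 10 below 0 on each. Cells of a mesenchymal type among the NSC cultures are a candidate source, and miR-21, which such cells hold in abundance, had a change of -0.461 with a 95% interval of -2.01 to 1.09. That interval reaches beyond -1, so whether such cells were present cannot be told apart from expression of these miRNAs by the NSC themselves. In the NSC group miR-9, abundant in the developing brain, was detected in 1 of 3 samples, while miR-199a-3p and miR-214 were detected in all 3. The identity of the NSC cultures was not tested, so the changes may not reflect differentiation alone. Of the 10 tested members of the list, 4 (miR-143, miR-145, miR-21 and miR-31) are also on the glial list, and NSC replicate 3 held the highest miR-199a-3p (14.51, against 11.47 and 12.32 in NSC replicates 1 and 2).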
